A study of Oryza sativa with 12 samples.

How the data were processed

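Total RNA from embryonic axes of rice seed (cultivar Nipponbare; the tissue label reads seed) was measured on 12 Affymetrix Rice Genome Arrays. Per the labels, seeds were equilibrated for 3 days at 25 °C, then kept at 25 °C (control) or at 40 °C under 85% relative humidity for 14 days by the protocol or 15 days by the description, and then kept for 3 days at 32% relative humidity. The sample titles separate each temperature into arrays with the suffix 0H (the 25 °C titles write it with the letter O, the 40 °C titles with the digit) and 4H, with 3 numbered replicates each; the labels neither define the suffixes nor say whether the replicates came from independent seed lots. RNA amounts of 26 to 82 µg and 20 µg of cRNA are stated. A condition at 45 °C that the labels name was not analysed here. The deposited values are log2 signals that the authors made with GCRMA (background correction with probe sequence, normalization across arrays and summary per probe set); the authors' notes name GCRMA without a version, and the log base was read from the values.

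The table held 57381 probe sets. The 123 control probe sets were left out of the gene tests and read separately, and probe sets were kept if they lay above log2 4 in at least 3 arrays, which left 17650 of 57258. The median of each array lay between 1.49 and 1.59, and the number of arrays limits the precision. Changes were tested with limma 3.58.1 in R 4.3.3 on all 12 arrays: lmFit with the group means, contrasts between them, eBayes with a trend in the variance, two-sided, with 8 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 within each comparison. The comparisons were 40 °C with 25 °C at 0H and at 4H, 4H with 0H at 25 °C and at 40 °C, the temperature effect averaged over 0H and 4H, and the difference of the temperature effects (the interaction). Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for the annotation and the plots. The fit was tested on simulated data with changes of 1 and 2 on the log2 scale, sizes chosen after a first run with smaller ones: for a comparison of 3 with 3 arrays it recovered 88 and 99 of 100 changed probe sets with 13 false calls among 210, and for the interaction 71 and 97 of 100 with 5 false calls among 176. The simulated noise was independent between probe sets, and few probe sets changed, with a small list shifted by less besides. Noise that the probe sets of an array have in common was not simulated, so the false calls it may give were not tested.

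Of the probe sets 22436 were paired with exactly 1 gene, 95 with several and 34850 were not listed in the annotation. The pairs covered 17905 genes, of which 2445 had a usable short name in a RefSeq table of the rice assembly ASM3414082v1, which was used for names only; the authors name no genome build, so no coordinates are given. Gene lists (44 with at least 3 genes) were tested with limma's camera at a preset correlation of 0.01 on 11516 genes, 1 probe set per gene (the one with the highest mean), with adjustment over the 44 lists of a comparison, and again with an estimated correlation. The subjects of 28 lists were fixed before the data were examined, and 16 were added from the annotation. All lists were translated into gene symbols after the annotation tables were read and before any value was looked at. A list thus holds only the kept genes whose symbol or synonym matched, and its counts do not describe a whole gene family. The genes named in each pairwise comparison were, by a rule fixed before the data were examined, the 10 largest rises and the 10 largest falls among adjusted calls with all 3 arrays of a group above all 3 of the other, and for the interaction the 5 largest each way; for each list up to 4 members with the lowest p could be named. The rule asked for a description that is not empty, which was read as a usable short name.

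The replicate numbers were checked for pairing from the data, since the labels do not say that they pair the arrays. For 4H with 0H at 25 °C the correlations across genes of the deviations of same-numbered replicates were 0.229, 0.126 and 0.423. All lay above the limit of 0.1 that was set, so the numbers could be read as pairs in that comparison. Replicate 2, however, correlated more with an array of another number (0.192). The reported changes, SE and p of every comparison, this one included, come from the fit without pairing. A fit with the replicate number as a block was run as an alternative, there and for the other comparisons. Control probe sets (3′ minus 5′ differences, spike-ins and ribosomal RNA) were compared with exact permutation tests. The alternatives fixed before the data were examined were no filter, a filter at log2 6, quantile normalization, eBayes without trend, array weights, the replicate block, a fit of only the 2 groups compared, the estimated correlation and leaving out each array in turn. Median centring of every count, setting every value below log2 4 to 4, and leaving out replicate 3 of both 25 °C groups (called the spike-in-low arrays, since their hybridisation spike-ins read lowest within their own groups, though 2 of the 40 °C 0H arrays read lower than the 25 °C one at 0H) or replicates 1 and 2 of the 40 °C 0H group (high poly-A spike-ins), were chosen after seeing the data. A change from or to a group with all arrays below log2 4 was bounded as the mean of the other group minus 4. Where a group was left with 1 array, that array was assumed to vary like the other groups. Other splits of the arrays were fitted in the same way.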

Results

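The transcript levels of rice embryonic axes (Oryza sativa, cultivar Nipponbare) were measured on 12 Affymetrix Rice Genome Arrays, and each probe set was read as a log2 signal. The arrays formed 4 groups of 3 replicates. Seeds had been kept at 25 °C, the control, or at 40 °C under 85% relative humidity, and the labels of each temperature carry the suffix 0H or 4H, which the labels do not define. The median signal over all probe sets lay between 1.49 and 1.59 in every array, and 25.5% to 27.7% of the probe sets lay above log2 4. The number of arrays limits the precision. The first principal component held 81.2% of the variance and separated the 4H arrays from the 0H arrays, and the second held 13.6% and separated the temperatures among the 4H arrays. Replicate 1 of the 25 °C 0H group lay nearest to the 4H arrays, at −99.0 on the first component, against −105 and −112 for the other replicates of that group. The correlation across genes between single arrays was 0.970 to 0.985 between the temperatures at 0H and 0.846 to 0.878 at 4H; genes are not independent replicates. The p-values below measure the spread between these samples, which may be technical. All tests were two-sided. Log2 4 was the limit of the filter and not a measured background. Where all 3 arrays of the lower group lay below it, a change is given as at least its size against log2 4, and its p is that of the signals as deposited. Where both groups had means below it, the means are given and no size. Some probe sets, marked _s_at or _x_at by the manufacturer, can match related transcripts. Each gene list holds only the kept genes whose symbols matched, so its counts do not describe a whole gene family.

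**Figure D1:**
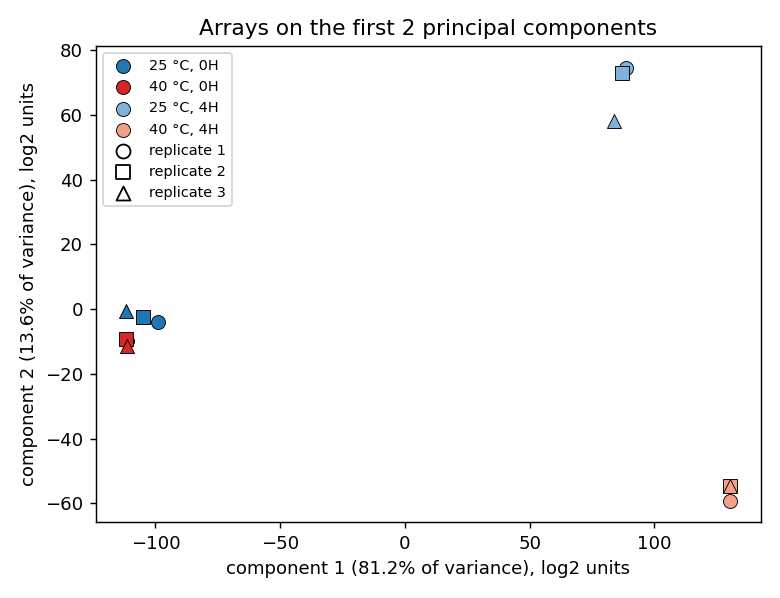
Position of the 12 arrays on the first and second principal component of the kept probe sets (log2 units); color marks the group and shape the replicate. The 0H arrays of both temperatures lie close together, from −112 to −99.0 on the first component, and the 4H groups lie apart from each other on the second.

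The comparison of 40 °C with 25 °C at 0H set the transcripts of axes from both storage temperatures side by side. The 3′ minus 5′ signals of Gapdh and Actin, given below, also lay apart between these groups. A change with storage and a difference in RNA quality or preparation were therefore not told apart at 0H. GBSS1, the granule-bound starch synthase that makes amylose, was 4.91-fold higher at 40 °C (log2 change 2.30, SE 0.26, adjusted p = 7.45e-05), from 6.46 ± 0.55 to 8.76 ± 0.16 (SD, n = 3). The seed storage transcripts RA14, a seed albumin, and PROLM25, a prolamin, rose by 1.44 (SE 0.31) and 1.30 (SE 0.30). The membrane receptor gene ADIPOR1 rose by at least 1.40, the mitochondrial cytochrome b transcript cob by 1.07 and the starch synthase SSII-3 by at least 0.57. The remaining named rises were BIPP2C1 (0.84), CML27 (at least 0.26), OsCDSP32 (means 2.70 and 3.52, both below log2 4) and the phosphate transporter OsPht1;4 (0.76). Among the falls were 3 transcripts of 12-oxophytodienoate reductases, a family that includes enzymes of jasmonate synthesis: OPR1 fell by at least 1.16 and OPR10 by at least 0.54, and OPR5 read 3.67 at 25 °C and 2.11 at 40 °C, both below log2 4 (adjusted p = 9.50e-06). GH3.5 (also JAR1), which joins jasmonate to amino acids, fell by 1.08 (SE 0.14), and the proteasome ATPase OsRPT1b fell by 1.61 (SE 0.20). The transcription factor NAC067 read 3.72 and 1.81, with means below log2 4. The chloroplast ATP synthase transcript atpI (−1.43), the transporter ABCG39 (means 3.88 and 2.57, both below log2 4), the DNA polymerase OsPolL (at least 0.28 lower) and the phosphatase OsPP2C32 (−0.92) completed the named falls. By the rule for naming them, all 3 arrays of a temperature lay above all 3 of the other in each of these genes.

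Replicate 1 of the 25 °C group read high for some of these genes, with NAC067 at 5.70 against 3.27 and 2.19 in the other replicates. Without it the 25 °C mean of NAC067 was 2.73 (adjusted p = 0.0146), the fall of OPR1 was at least 0.49 (adjusted p = 0.000430), and OPR10, with a 25 °C mean of 3.99, had no size (adjusted p = 0.0541). Without that array OsPolL fell by at least 0.19. Without replicate 3 at 25 °C NAC067 fell by at least 0.49, and without replicate 2 at 25 °C OPR10 fell by at least 0.82. Without replicate 1 or 2 at 40 °C CML27 rose by at least 0.13 or 0.43. Over all alternatives the adjusted p of NAC067, OPR1 and OPR10 reached 0.275, 0.0936 and 0.430. OPR10, NAC067 and OsPht1;4 also lost their calls without 1 of several other arrays, where the SE was larger (0.36 to 0.37 against 0.32, 0.65 against 0.56 and 0.24 to 0.25 against 0.22). In these cases the fall of OPR10 was at least 0.54, the 2 means of NAC067 stayed below log2 4, and OsPht1;4 differed by 0.62 to 0.80. With all values below log2 4 set to 4, the calls of OPR1, OPR5, OPR10, NAC067, ABCG39, CML27 and OsCDSP32 ended (adjusted p from 0.0593 to 1). Storage transcripts read high in replicate 3 of the 25 °C group, with RA14 at 9.87 against 8.65 and 8.99, and without that array the rise of GBSS1 was 2.61.

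The lipoxygenase and jasmonate pathway list was the 1 of 44 lists that was called at 0H. Of its 21 genes 7 fell, 14 did not pass the test and 0 rose (8 fell adjusted over the list alone; median log2 change −0.19, adjusted p = 0.00268, adjusted p = 0.904 with an estimated correlation). With values below log2 4 set to 4 it was not called (median −0.07, adjusted p = 0.106, range 0.000134 to 0.106 over its alternatives). Besides OPR5, GH3.5 and OPR1, the reductase OPR4 fell by 0.88 (SE 0.16). The seed storage protein list was not called (adjusted p = 0.0895), and RA14 and PROLM25 were the 2 of its 8 genes that rose (3 adjusted over the list alone). The starch synthesis list was not called either (adjusted p = 0.363), although 3 of its 9 genes rose, among them the branching enzyme SBE by 0.68 (SE 0.10), and SSS1 fell by 0.22 (SE 0.06). None of the 4 alpha-amylase transcripts passed the test over all genes, while 2 were higher adjusted over the list alone (AMY1.2 at 0.75, SE 0.25; list adjusted p = 0.0848). No gene of the small heat shock list (18 genes) or of the late embryogenesis abundant list (9 genes) passed the test at 0H, with list adjusted p of 0.379 and 0.987. Among 19 heat stress transcription factors 4 fell, such as HSFA9 (−0.44, SE 0.08) and HSFA2D (−0.60, SE 0.12), and 1 rose (7 and 3 adjusted over the list alone; list adjusted p = 0.379). Of 20 antioxidant genes 3 fell and 1 rose (5 and 1 adjusted over the list alone; list adjusted p = 0.399): CAT-A, a catalase, fell by 0.72 (SE 0.15), and PRXIIF rose by 0.41 (SE 0.13).

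In all, 3129 of 17650 probe sets (17.7%) changed at 0H by limma, 1058 of them higher and 2071 lower at 40 °C. Of these 394 changed more than 2-fold, and in 179 all arrays of both groups lay below log2 4. The groups did not overlap in 37.1% of the probe sets, where chance gives 10%. Of the 32 tests of control probe sets, 8 measures in 4 comparisons, none passed adjustment: the lowest exact permutation p was 0.1, the smallest that 3 against 3 can give (adjusted p = 0.229). At 0H the 3′ minus 5′ signal of Gapdh was 2.24 ± 0.17 at 25 °C and 3.66 ± 0.29 at 40 °C (SD, n = 3; exact permutation p = 0.1). With the same p, the 3′ minus 5′ signal was 2.44 and 3.33 for Actin and −0.66 and −0.52 for Ubiquitin, and the ribosomal RNA controls read 11.8 and 9.67 (18S) and 12.4 and 11.5 (28S); the other 3 measures had a p of 0.2 to 0.3. The poly-A spike-ins read 8.82 and 8.85 in replicates 1 and 2 at 40 °C against 4.83 in replicate 3. The count was 2079 without replicate 2 at 40 °C, 2080 without replicate 2 at 25 °C, 888 with replicates 1 and 2 at 40 °C left out together and 5558 with array weights. With those 2 arrays left out, 1 array was left at 40 °C, and the calls of 12 of the named genes ended (adjusted p from 0.0623 to 0.430). Their differences were 1.49 for RA14 (SE 0.47, against 0.31), 1.41 for PROLM25 (SE 0.47, against 0.30), 1.05 for cob, 0.68 for OsPht1;4, −1.18 for atpI and −0.67 for OsPP2C32, and at least 0.51 up for SSII-3, 1.16 down for OPR1 and 0.54 down for OPR10. OsCDSP32, NAC067 and ABCG39 had means below log2 4 in both groups. The SE of each of the 12 was larger than with all arrays. The number of called lists was 3 without replicate 1 at 25 °C or replicate 2 at 40 °C, and 2 without replicate 3 of either temperature.

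**Figure D2:**
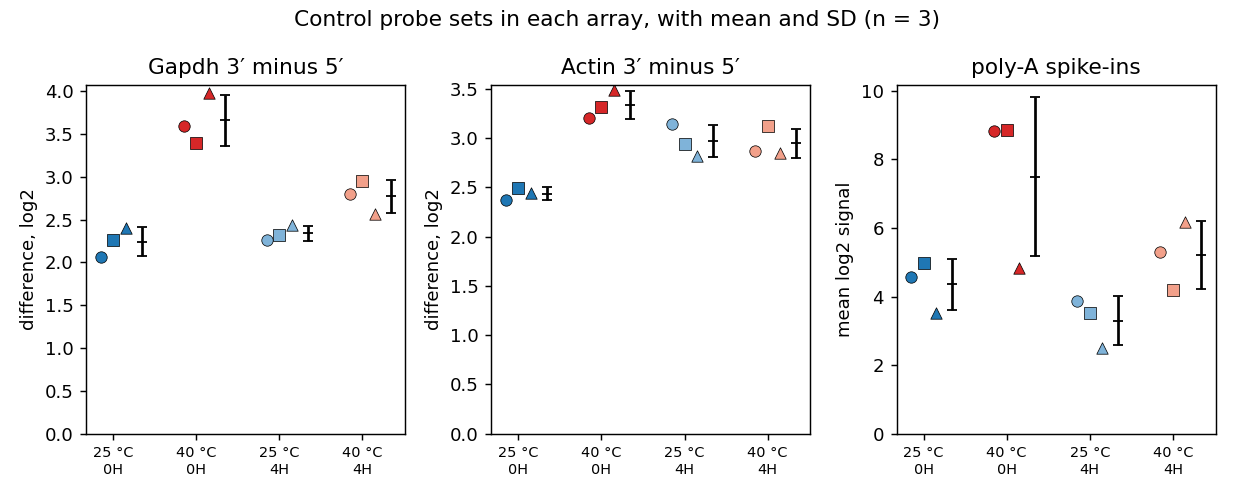
Control probe sets of each array (points, shape by replicate) with the mean and SD of each group (bars, n = 3): the 3′ minus 5′ difference of Gapdh and of Actin (log2) and the mean log2 signal of the poly-A spike-ins. The Gapdh difference at 0H was 2.24 at 25 °C and 3.66 at 40 °C, and at 4H 2.34 and 2.77.

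At 4H the same comparison of 40 °C with 25 °C gave larger changes. The 3′ minus 5′ signal of Gapdh and the poly-A spike-ins, given below, lay apart here too. A change with storage was therefore not told apart from a difference in RNA quality or preparation at 4H either. DREB1A, a transcription factor of cold and drought responses, was 12.3-fold higher at 40 °C (log2 change 3.62, SE 0.31, adjusted p = 9.29e-08), from 5.98 ± 0.68 to 9.60 ± 0.23 (SD, n = 3). The heat stress factor HSFA2C, at a locus that the name table also calls ARD1, rose by 2.84 (SE 0.16), DREB2B by 2.66 (SE 0.16) and the calmodulin-like CML31 by 3.38 (SE 0.20). The expansin EXPA29, of a family that loosens cell walls, was 12.9-fold lower (−3.69, SE 0.11, adjusted p = 3.01e-11), from 9.22 ± 0.16 to 5.53 ± 0.21 (SD, n = 3). OsWOX11, a homeobox gene of crown root development, fell by 3.63 (SE 0.10), and the sucrose synthases OsSUS2 and OsSUS1, which cleave sucrose, changed by −3.41 (SE 0.24) and −3.27 (SE 0.24). The other named rises were cob (3.33), KIN8B (at least 1.72), the formin FH16 (2.71), OsSAP17 (2.70), OsPP2C36 (2.64) and OsPP2C32 (2.63). The other named falls were C6-oxidase, the brassinosteroid enzyme DWARF (−3.09), and, by at least the size given, the phenylalanine ammonia-lyase PAL (2.54), OsYAB7 (2.21), CAD3 (1.44), the auxin-conjugating GH3.4 (0.93) and AtbHLH004 (0.56). The same rule required all 3 arrays of a temperature above all 3 of the other.

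Small heat shock proteins, which bind unfolding proteins, rose at 40 °C in 16 of 18 genes and fell in 2 (median 1.18, adjusted p = 0.000362, adjusted p = 0.521 with an estimated correlation). HSP26.2 rose by 1.37 (SE 0.07), HSP17.9B by 1.21 (SE 0.11), HSP24.1 by 1.15 (SE 0.14) and HSP17.4 by 1.37 (SE 0.18). These values compare the temperatures at 4H. Several members fell from 0H to 4H at 40 °C too, by less than at 25 °C. At 40 °C HSP26.2 went from 9.34 to 8.74, HSP16.0 from 7.34 to 5.35 and HSP17.8 from 8.12 to 6.56. HSP17.9B, which rose by 4.55 (SE 0.11) from 0H to 4H at 40 °C, and HSP18.8 went the other way. Replicate 3 of the 25 °C arrays read HSP17.8 at 5.93, against 2.98 and 3.76 in the other replicates. Heat stress factors rose in 12 of 19 genes and fell in 3 (median 0.97, adjusted p = 0.00472, adjusted p = 0.486 with an estimated correlation). HSFA9 changed by 1.67 (SE 0.08) and HSFA4B by 2.38 (SE 0.14). Cytosolic ribosomal proteins fell in 21 of 22 genes (median −0.72, adjusted p = 0.000362, adjusted p = 0.486 with an estimated correlation). RPL3 changed by −0.95 (SE 0.06) and RPS4 by −1.09 (SE 0.07). All 14 proteasome subunits fell (median −0.55, adjusted p = 0.00760, adjusted p = 0.486 with an estimated correlation). OsPAE1 changed by −1.43 (SE 0.08) and OsPBB1 by −1.09 (SE 0.07). In the glycolysis and fermentation list 13 of 16 genes fell and 1 rose (median −0.87, adjusted p = 0.0187, adjusted p = 0.486 with an estimated correlation). GAPC changed by −1.34 (SE 0.07) and the enolase Eno1 by −1.06 (SE 0.07). Expansins and xyloglucan endotransglucosylases fell in 11 of 15 genes and rose in 1 (median −1.65, adjusted p = 0.0359, adjusted p = 0.486 with an estimated correlation). EXPB3 fell by at least 0.48.

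All 6 methionine sulfoxide reductases, which repair oxidised methionine, fell at 40 °C (median −0.99, adjusted p = 0.0359, adjusted p = 0.486 with an estimated correlation). MSRA2-1 changed by −1.68 (SE 0.09) and MSRB1 by −1.58 (SE 0.08). Protein disulfide isomerases, which form disulfide bonds in the endoplasmic reticulum, fell in 8 of 9 genes (median −0.99, adjusted p = 0.0268, adjusted p = 0.486 with an estimated correlation). OsPDIL1-1 changed by −1.31 (SE 0.11). All 5 listed WRKY factors rose (median 1.09, adjusted p = 0.0214, adjusted p = 0.486 with an estimated correlation). OsWRKY76 rose by 2.34 (SE 0.28). Of 4 NAC factors 3 rose (4 adjusted over the list alone; median 1.28, adjusted p = 0.0339, adjusted p = 0.486 with an estimated correlation). NAC071 rose by 1.59 (SE 0.12), and NAC067, which did not pass the test, differed by 1.22 (SE 0.56, adjusted p = 0.0611). The SE of NAC067 draws on all 4 groups, and its SD was 1.80 in the 25 °C 0H group but 0.08 in each 4H group. Stress-associated zinc finger proteins rose in 7 of 11 genes and fell in 2 (median 0.89, adjusted p = 0.0268, adjusted p = 0.486 with an estimated correlation). OsSAP7 rose by 1.91 (SE 0.19). Calcium-dependent and CBL-interacting kinases rose in 20 of 39 genes and fell in 10 (median 0.30, adjusted p = 0.0359, adjusted p = 0.486 with an estimated correlation). CPK4 changed by 2.47 (SE 0.18). In the list of ethylene synthesis, response and DREB factors 6 of 11 genes rose and 2 fell (median 0.46, adjusted p = 0.0371, adjusted p = 0.521 with an estimated correlation). The receptor ERS1 rose by 0.59 (SE 0.07) and EIN2, a central signalling protein, fell by 0.76 (SE 0.12). Except for the NAC factors, the counts of these lists were the same when adjusted over the list alone. Among lists that were not called, all 6 chitinases and pathogenesis-related genes fell (list adjusted p = 0.0899), and PBZ1 changed by −2.36 (SE 0.28). Of 20 antioxidant genes 13 fell and 2 rose (list adjusted p = 0.273), and APX6 changed by −1.49 (SE 0.09).

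At 4H 13068 probe sets (74.0%) changed by limma, 5384 higher and 7684 lower at 40 °C, and 4748 changed more than 2-fold; in 473 all arrays of both groups lay below log2 4. At 4H the groups did not overlap in 76.3% of the probe sets, where chance gives 10%. The 3′ minus 5′ signal of Gapdh was 2.34 ± 0.09 at 25 °C and 2.77 ± 0.20 at 40 °C (SD, n = 3; exact permutation p = 0.1, adjusted p = 0.229), and that of Actin 2.97 ± 0.16 and 2.95 ± 0.15 (exact permutation p = 0.9). The poly-A spike-ins read 3.30 and 5.23 (exact permutation p = 0.1, adjusted p = 0.229), and the other 5 measures had a p of 0.4 to 0.8. With all probe sets tested, the NAC and the expansin lists were not called (medians 0.57 and −0.34, adjusted p = 0.235 and 0.126), and the ethylene list was not called without replicate 2 at 25 °C (median 0.54, adjusted p = 0.0510). Over their alternatives the adjusted p of these 3 lists ranged from 0.0224 to 0.235, from 0.0219 to 0.126 and from 0.0225 to 0.0510.

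**Figure D3:**
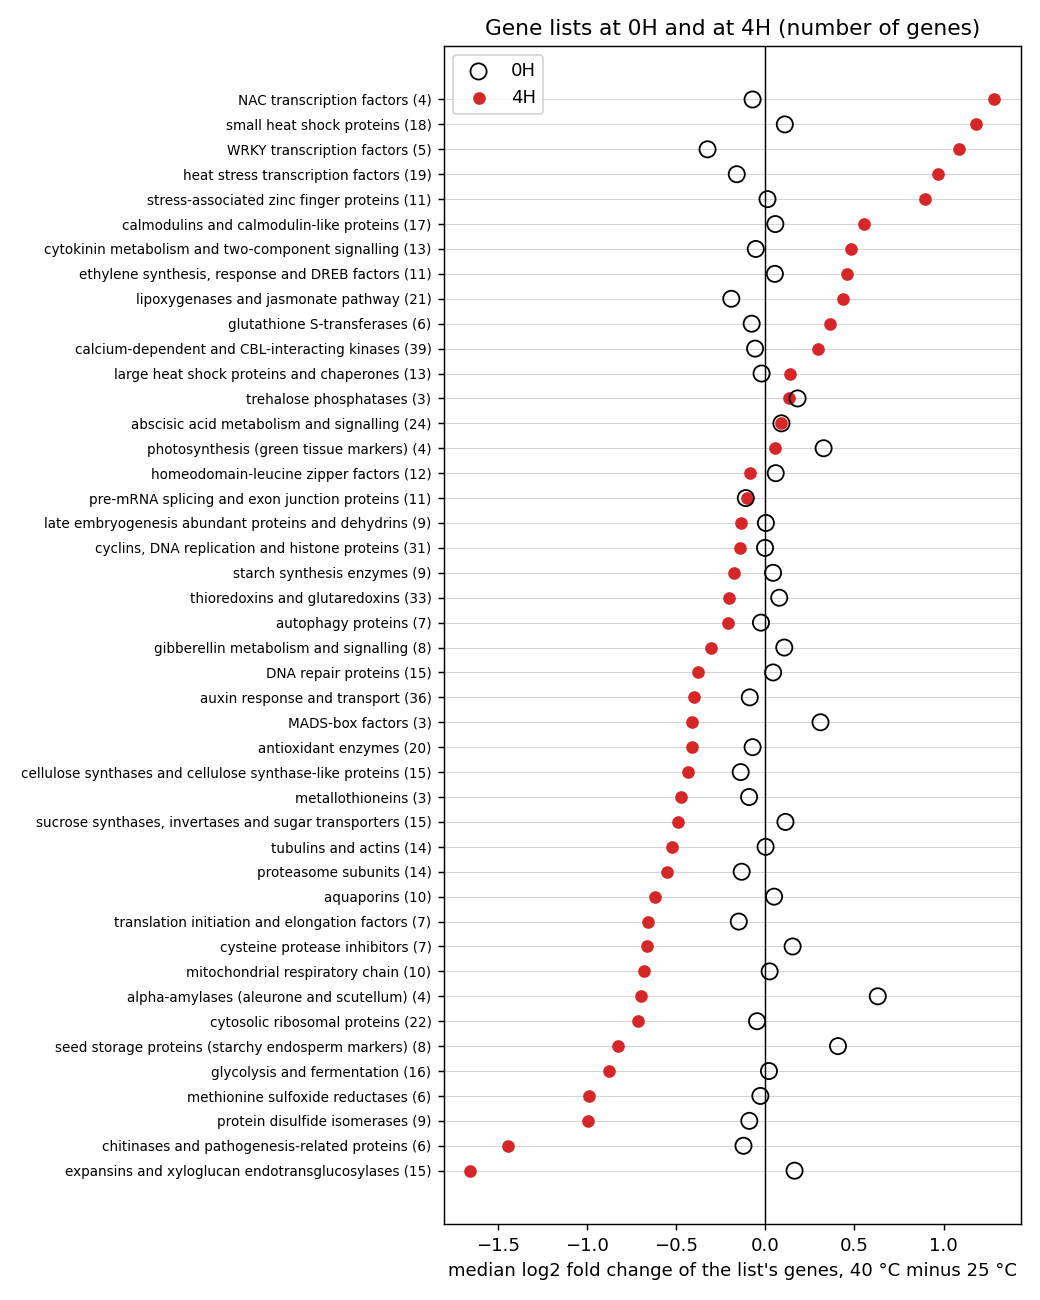
Median log2 change of each gene list from 25 °C to 40 °C, at 0H (open circles) and at 4H (red points), with the number of genes of each list in parentheses. At 4H the medians run from −1.65 for the expansin list to 1.28 for the NAC list, and at 0H the jasmonate list, at −0.19, was the 1 list called.

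The comparison of 4H with 0H at 25 °C described the change between the suffix groups in axes kept at the lower temperature. The nonsymbiotic hemoglobins NSHB2 and NSHB1 rose by at least 6.67 (adjusted p = 6.82e-11) and at least 6.09 (adjusted p = 2.22e-15), and NSHB2 went from 2.37 ± 0.96, below log2 4, to 10.7 ± 0.02 (SD, n = 3). PDC1, a pyruvate decarboxylase of fermentation, rose by 6.08 (SE 0.25) and OPR1 by 6.05 (SE 0.37). OPR5 rose by at least 5.83, the metal-nicotianamine transporter gene osysl12 by at least 5.29, cap2 by at least 5.21, the auxin-conjugating GH3.2 by at least 4.05 and the xylanase inhibitor Chib3H-a by at least 2.86. NAC067, above log2 4 in 1 of the 3 arrays at 0H, rose by 5.97 (SE 0.56), and by at least 5.69 without that array. Among the named falls were the small heat shock gene HSP17.8 (−3.75, SE 0.53, adjusted p = 1.04e-05; above log2 4 in 1 of the 3 arrays at 4H, replicate 3, and at least 3.97 lower without it), cob (−3.60), HSP21.9 (−3.47) and HSP16.0 (−3.18, and at least 3.06 lower without replicate 3 at 4H). HSFC2A (−3.05), MSH5 (−3.03) and the ethylene receptor ETR4 (−3.01) also fell, as did the protease gene FTSH6 by at least 3.16, ILL8 by at least 1.96 and the alpha-amylase AMY1.2 by at least 1.45.

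At 25 °C the jasmonate list rose in 17 of 21 genes and fell in 2 (median 1.70, adjusted p = 0.00304, adjusted p = 0.422 with an estimated correlation). The jasmonate repressor genes JAZ6 and JAZ7 rose by 4.43 (SE 0.18) and by at least 2.98. Expansins and xyloglucan endotransglucosylases rose in 12 of 15 genes and fell in 2 (median 2.87, adjusted p = 0.0199, adjusted p = 0.403 with an estimated correlation). EXPB4 rose by at least 2.76 and OsXTH8 by at least 2.52. Cellulose synthases and related proteins rose in 12 of 15 genes and fell in 2 (median 1.73, adjusted p = 0.0213, adjusted p = 0.442 with an estimated correlation). CSLC7 rose by at least 2.94 and CESA1 by 2.66 (SE 0.10). Stress-associated zinc finger proteins rose in 9 of 11 genes and fell in 1 (median 1.13, adjusted p = 0.0199, adjusted p = 0.523 with an estimated correlation). OsSAP11 changed by 3.48 (SE 0.17). All 5 listed WRKY factors rose (median 2.59, adjusted p = 0.0223, adjusted p = 0.403 with an estimated correlation). Calcium-dependent and CBL-interacting kinases rose in 27 of 39 genes and fell in 9 (median 0.82, adjusted p = 0.0217, adjusted p = 0.422 with an estimated correlation). Small heat shock proteins fell in 16 of 18 genes (median −1.40, adjusted p = 0.0199, adjusted p = 0.678 with an estimated correlation). HSP17.9B and HSP18.8 rose by 3.39 (SE 0.11) and by at least 3.16. Starch synthesis enzymes fell in 8 of 9 genes (median −1.37, adjusted p = 0.0223, adjusted p = 0.403 with an estimated correlation). DPE1 changed by −2.26 (SE 0.12). Adjusted over the list alone, 8 fell and 1 rose. All 9 late embryogenesis abundant genes, whose proteins accumulate in dry seed, fell (median −0.47, adjusted p = 0.0249, adjusted p = 0.532 with an estimated correlation). RAB16D changed by −2.28 (SE 0.14) and Dhn1 by −1.14 (SE 0.09). The other counts of this comparison were the same when adjusted over the list alone.

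In all, 14457 probe sets (81.9%) changed between 4H and 0H at 25 °C by limma, 7044 higher and 7413 lower at 4H, 7741 of them more than 2-fold; in 315 all arrays of both groups lay below log2 4. Of the control measures, the 18S and 28S ribosomal RNA read 11.8 and 12.4 at 0H against 9.64 and 10.97 at 4H, and the 3′ minus 5′ signal of Actin was 2.44 against 2.97 (exact permutation p = 0.1 and adjusted p = 0.229 for each). That of Gapdh was 2.24 and 2.34 (exact permutation p = 0.5), and the other 4 measures had a p of 0.2 to 0.6. These groups did not overlap in 81.9% of the probe sets, where chance gives 10%. Since the ribosomal RNA and Actin controls lay apart, a change between the suffix groups was not told apart from a difference in RNA quality or preparation. Centring each array on its median moved the median change of all probe sets from −0.04 to −0.14, and the late embryogenesis abundant list was not called after quantile normalization (median −0.29, adjusted p = 0.0892, with a range from 0.00953 to 0.0892 over its alternatives).

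At 40 °C the change from 0H to 4H included NAC067, which rose by at least 6.91 (adjusted p = 6.40e-10), from 1.81 ± 0.09, below log2 4, to 10.9 ± 0.1 (SD, n = 3). By at least the size given, OPR1 (7.71), OPR10 (7.09), DREB1B (6.50), the transporter gene osysl12 (5.97), OPR5 (5.90), SAT4 (4.95), CML31 (4.75) and BC1L9 (3.93) also rose. The GRAS factor CIGR2 rose by 6.47. ETR4 changed by −4.09, HSFC2A by −3.84 (SE 0.12), the thioredoxin gene OsTrx26 by −3.66 and CPDK2 by −3.63. OsSPP1 fell by at least 3.34, the DNA damage sensor NBS1 by at least 2.58 and AMY1.2 by at least 2.20. ILL8 fell by at least 1.89, the polyamine transporter gene OsPUT1 by at least 1.47 and the ascorbate peroxidase APX8 by at least 1.30.

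The jasmonate list rose in 17 of 21 genes and fell in 4 at 40 °C (median 2.31, adjusted p = 0.00118, adjusted p = 0.461 with an estimated correlation). JAZ6 changed by 6.28 (SE 0.18) and GH3.5 by 4.26 (SE 0.14). Cytosolic ribosomal proteins fell in 21 of 22 genes (median −0.98, adjusted p = 0.00118, adjusted p = 0.494 with an estimated correlation). RPS4 changed by −1.30 (SE 0.07). Stress-associated zinc finger proteins rose in 10 of 11 genes and fell in 1 (median 1.84, adjusted p = 0.00568, adjusted p = 0.494 with an estimated correlation). OsSAP17 rose by at least 5.84. All 5 listed WRKY factors rose (median 3.06, adjusted p = 0.0104, adjusted p = 0.461 with an estimated correlation). OsWRKY24 rose by at least 4.35. Calcium-dependent and CBL-interacting kinases rose in 23 of 39 genes and fell in 9 (median 1.11, adjusted p = 0.0104, adjusted p = 0.461 with an estimated correlation). CPK13 changed by 4.40 (SE 0.11). All 9 starch synthesis enzymes fell (median −1.71, adjusted p = 0.0413, adjusted p = 0.461 with an estimated correlation). DPE1 fell by 2.98 (SE 0.12). The ethylene list rose in 9 of 11 genes and fell in 2 (median 1.36, adjusted p = 0.0454, adjusted p = 0.641 with an estimated correlation). The receptor ETR2 rose by at least 4.33 while ETR4 fell. DNA repair genes fell in 13 of 15 and rose in 2 (median −1.94, adjusted p = 0.0492, adjusted p = 0.494 with an estimated correlation). PARP3 fell by 2.87 (SE 0.09). All 9 late embryogenesis abundant genes fell (median −0.70, adjusted p = 0.0492, adjusted p = 0.644 with an estimated correlation). RAB16D changed by −2.78 (SE 0.14). All 4 listed NAC factors rose (median 3.20, adjusted p = 0.0492, adjusted p = 0.494 with an estimated correlation). Cellulose synthases and related proteins rose in 10 of 15 genes and fell in 4 (median 1.96, adjusted p = 0.0492, adjusted p = 0.494 with an estimated correlation). Adjusted over the list alone, these counts were the same.

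In all, 15396 probe sets (87.2%) changed between 4H and 0H at 40 °C by limma, 7231 higher and 8165 lower at 4H, 10096 of them more than 2-fold; in 228 all arrays of both groups lay below log2 4. The 3′ minus 5′ signals were 3.66 at 0H and 2.77 at 4H for Gapdh, 3.33 and 2.95 for Actin and 0.88 and 0.44 for Cyclophilin, and the hybridisation spike-ins read 8.53 and 9.12 (exact permutation p = 0.1 and adjusted p = 0.229 for each). The 3′ minus 5′ signal of Ubiquitin was −0.52 and −0.60 (exact permutation p = 0.3), and the other 3 measures had a p of 0.2 to 1. These groups did not overlap in 89.4% of the probe sets, where chance gives 10%. With the Gapdh, Actin and Cyclophilin signals apart, a change from 0H to 4H was not told apart from a difference in RNA quality or preparation. The calls of the DNA repair, late embryogenesis abundant, NAC and cellulose synthase lists ended after quantile normalization and after median centring, with medians of −1.98 and −1.99, −0.53 and −0.75, 3.14 and 3.15, and 1.90 and 1.91, and adjusted p of 0.0551 and 0.0546, 0.0969 and 0.0638, 0.0529 and 0.0503, and 0.0551 and 0.0543. They also ended with values below log2 4 set to 4 (medians −1.004, −0.70, 2.40 and 0.76), and over all alternatives the adjusted p ranged from 0.0133 to 0.0684, 0.0133 to 0.0969, 0.0356 to 0.0566 and 0.0401 to 0.151. The ethylene list was not called without replicate 3 of the 0H arrays (median 1.37, adjusted p = 0.0506, range 0.0133 to 0.0506). Of the 11 called lists 6 were called without replicate 3 of the 0H arrays, and 7 without replicate 2 of the 0H arrays or without replicate 1 or replicate 3 of the 4H arrays.

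**Figure D4:**
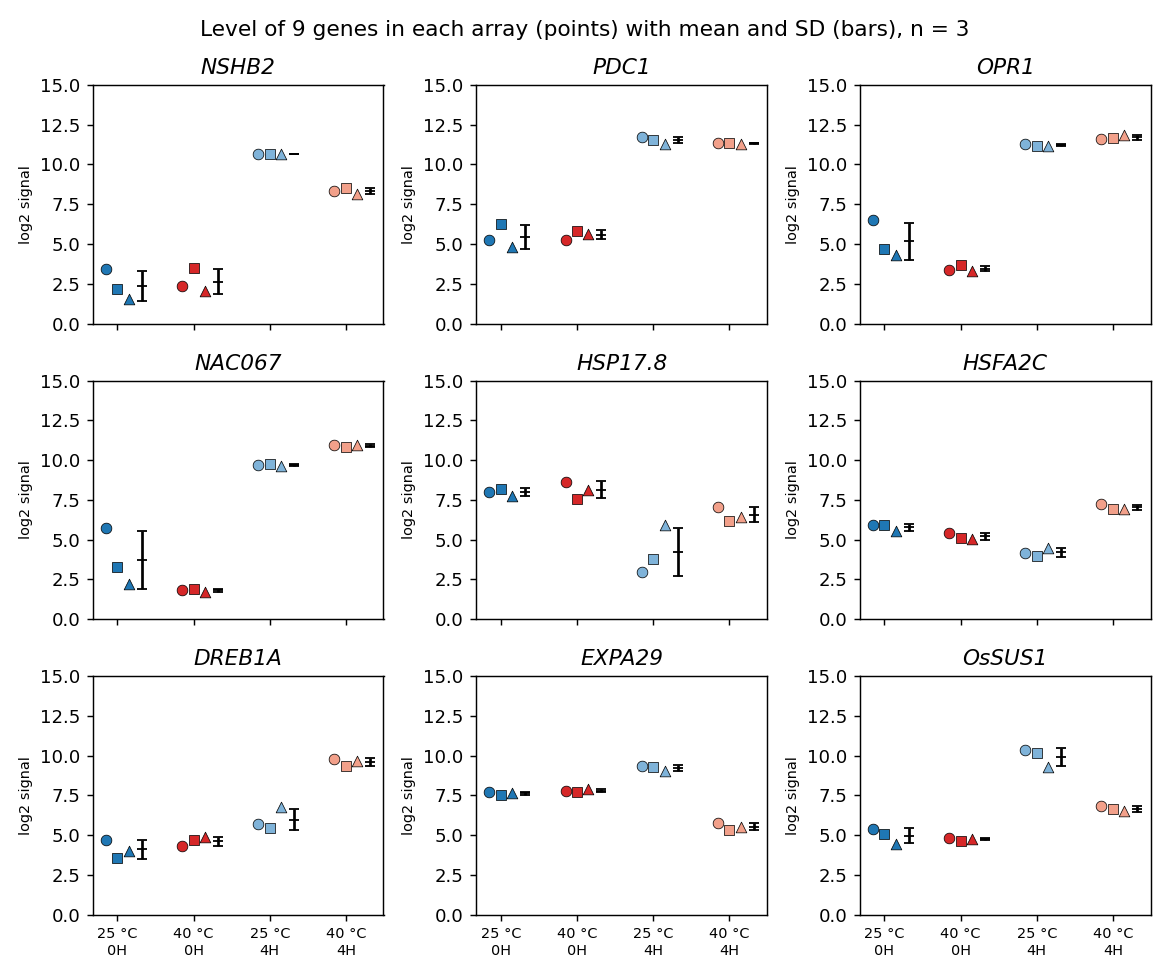
Log2 signal of 9 genes in each array (points, shape by replicate) with the mean and SD of each group (bars, n = 3). NSHB2, PDC1, OPR1 and NAC067 were higher at 4H than at 0H at both temperatures, and HSFA2C, DREB1A, EXPA29 and OsSUS1 differed between the temperatures at 4H.

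The changes from 0H to 4H at the 2 temperatures were correlated across genes (Pearson r = 0.831, Spearman rho = 0.836, jackknife SE over arrays 0.0173; genes are not independent replicates). Of the 7044 probe sets higher at 4H at 25 °C 5687 were also higher at 40 °C, where 2885.8 would be shared if the calls were independent, and of the 7413 lower 6349 were also lower, where 3429.3 would be. For the changes with temperature at 0H and at 4H the correlation was smaller than its SE (Pearson r = 0.0716, Spearman rho = 0.0529, jackknife SE over arrays 0.0794). Of the 1058 probe sets higher at 40 °C at 0H 420 were also higher at 4H (322.7 if independent) and 368 were lower. Of the 2071 lower at 0H 941 were also lower at 4H (901.6 if independent) and 579 were higher.

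Averaged over 0H and 4H, the small heat shock proteins rose at 40 °C in 15 of 18 genes and fell in 1 (16 and 1 adjusted over the list alone; median 0.63, adjusted p = 0.000427, adjusted p = 0.532 with an estimated correlation). HSP26.2 rose by 0.77 (SE 0.05). The ribosomal protein list fell in 20 of 22 genes (median −0.39, adjusted p = 0.000427, adjusted p = 0.492 with an estimated correlation). Adjusted over the list alone, 20 fell and 1 rose. All 14 proteasome subunits fell (median −0.37, adjusted p = 0.00190, adjusted p = 0.492 with an estimated correlation). Translation initiation and elongation factors fell in 6 of 7 genes (median −0.40, adjusted p = 0.0446, adjusted p = 0.492 with an estimated correlation). eIF-4A-1 changed by −0.60 (SE 0.04). Calmodulins and calmodulin-like proteins rose in 10 of 17 and fell in 5 (median 0.30, adjusted p = 0.0446, adjusted p = 0.533 with an estimated correlation). CML15 changed by 1.06 (SE 0.09). The heat stress factors rose in 11 of 19 genes and fell in 5 (median 0.47, adjusted p = 0.0122, adjusted p = 0.492 with an estimated correlation). The protein disulfide isomerase list fell in all 9 genes and the glycolysis and fermentation list in 13 of 16 (medians −0.50 and −0.45, adjusted p = 0.0122 for both, adjusted p = 0.492 with an estimated correlation for both). The ethylene list rose in 6 of 11 genes and fell in 0 (median 0.25, adjusted p = 0.0303, adjusted p = 0.532 with an estimated correlation). The stress-associated zinc finger list rose in 7 of 11 and fell in 2 (median 0.48, adjusted p = 0.0303, adjusted p = 0.499 with an estimated correlation). All 6 methionine sulfoxide reductases fell (median −0.52, adjusted p = 0.0446, adjusted p = 0.492 with an estimated correlation). By limma 11731 probe sets (66.5%) changed, 4684 higher and 7047 lower. Median centring ended the calls of the calmodulin, methionine sulfoxide reductase and translation factor lists (medians 0.37, −0.45 and −0.34; adjusted p up to 0.0702, 0.0845 and 0.0610 over their alternatives). Quantile normalization ended that of the zinc finger list (median 0.51, adjusted p = 0.0573, range 0.0114 to 0.0573).

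The difference of the temperature effects between 4H and 0H was tested as an interaction. CML31 (3.85, SE 0.28), OsPP2C32 (3.55, SE 0.30) and HSFA2C (3.42, SE 0.22) had the largest positive differences among the named genes, followed by KIN8B (3.35) and FH16 (3.31). OsPP2C32 fell at 0H and rose at 4H. With values below log2 4 set to 4, the difference was 3.38 for CML31, 1.72 for KIN8B and 2.99 for FH16, and −0.56 for AtbHLH004, −1.44 for CAD3 and −2.26 for OsYAB7, so these sizes depend on signals below that limit. EXPA29 (−3.85, SE 0.15, adjusted p = 2.04e-09) and OsWOX11 (−3.77, SE 0.14, adjusted p = 2.04e-09) had the largest negative differences, followed by AtbHLH004 (−3.56), CAD3 (−3.44) and OsYAB7 (−3.37). The effect on ribosomal proteins was more negative at 4H in 21 of 22 genes (median −0.67, adjusted p = 0.000602, adjusted p = 0.551 with an estimated correlation). It was more negative on glycolysis and fermentation in 13 of 16 genes and more positive on 1 (median −0.93, adjusted p = 0.0161, adjusted p = 0.554 with an estimated correlation), and on methionine sulfoxide reductases in all 6 (median −0.85, adjusted p = 0.0362, adjusted p = 0.554 with an estimated correlation). The effect was more positive at 4H in 11 of 19 heat stress factors and more negative in 2 (adjusted p = 0.00178, adjusted p = 0.551 with an estimated correlation). It was more positive in 14 of 18 small heat shock proteins and more negative in 2 (median 1.08, adjusted p = 0.00178, adjusted p = 0.554 with an estimated correlation). The jasmonate list was more positive in 14 of 21 genes and more negative in 6 (median 0.48, adjusted p = 0.0161, adjusted p = 0.551 with an estimated correlation). GH3.5 differed by 2.55 (SE 0.20). All 5 listed WRKY factors were more positive (median 1.05, adjusted p = 0.0141, adjusted p = 0.488 with an estimated correlation). So were all 4 listed NAC factors (median 1.54, adjusted p = 0.0189, adjusted p = 0.551 with an estimated correlation). Expansins and xyloglucan endotransglucosylases were more negative in 10 of 15 genes and more positive in 1 (median −1.79, adjusted p = 0.0171, adjusted p = 0.551 with an estimated correlation). The calcium kinase list was more positive in 17 of 39 genes and more negative in 9 (median 0.29, adjusted p = 0.0313, adjusted p = 0.551 with an estimated correlation). The zinc finger list was more positive in 6 of 11 genes and more negative in 1 (median 0.71, adjusted p = 0.0313, adjusted p = 0.554 with an estimated correlation). By limma 11469 probe sets (65.0%) differed, 4957 with a more positive and 6512 with a more negative effect at 4H. The counts of these 11 lists were the same when adjusted over the list alone. With all probe sets tested, the jasmonate, expansin and NAC lists were not called (medians 0.089, −0.49 and 0.54, adjusted p = 0.0723, 0.0572 and 0.151, the highest over their alternatives, whose lowest were 0.00647, 0.0111 and 0.0111). With values below log2 4 set to 4, the jasmonate and methionine sulfoxide reductase lists were not called (medians 0.46 and −0.63, adjusted p = 0.0592 for both; the latter ranged from 0.0109 to 0.0592).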

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

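Of the tests in this part, the comparison of 3′ and 5′ signals and the settings with median centring, with values below log2 4 set to 4 and with arrays left out by their spike-ins were chosen after the result was seen. The effect of temperature differed between 0H and 4H in 11469 probe sets and in 11 gene lists by the test of the difference itself, of which 0 were called with an estimated correlation. The named genes with the largest differences were CML31 (3.85), OsPP2C32 (3.55), HSFA2C (3.42), KIN8B (3.35) and FH16 (3.31), with a more positive effect at 4H, and EXPA29 (−3.85), OsWOX11 (−3.77), AtbHLH004 (−3.56), CAD3 (−3.44) and OsYAB7 (−3.37), with a more negative effect at 4H. Signals below log2 4 enter these sizes: with such values set to 4, the difference was 1.72 for KIN8B and −0.56 for AtbHLH004.

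Among control probe sets, which the gene tests do not use, the 3′ minus 5′ signal of Gapdh was higher at 40 °C by 0.92 over 6 against 6 arrays (2.29 ± 0.13 against 3.21 ± 0.54, SD; exact permutation p = 0.00216, adjusted over 8 measures p = 0.0173). That of Actin was higher by 0.44 (exact permutation p = 0.0303, adjusted p = 0.0808). The poly-A spike-ins were higher by 2.54 (exact permutation p = 0.0130, adjusted p = 0.0519). These permutations did not keep the 0H and 4H arrays apart. The difference was 1.41 at 0H and 0.43 at 4H for Gapdh, 0.90 and −0.02 for Actin, and 3.14 and 1.93 for the poly-A spike-ins.

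More probe sets changed between 40 °C and 25 °C at 4H than at 0H, by a ratio of 4.18. With the deposited values scaled again, the ratio was 4.20 with quantile normalization and 4.13 with median centring. The authors had already normalized these values across arrays, so this cannot decide whether their scaling was a cause. Without replicate 3 of both 25 °C groups, whose hybridisation spike-ins read lowest within their own groups, the ratio was 2.95. A loss of 5′ signal in the 40 °C arrays would have to be larger at 4H, but the 3′ minus 5′ signal at 40 °C minus that at 25 °C was smaller at 4H than at 0H (4H minus 0H −0.98, SE 0.23, for Gapdh and −0.92, SE 0.16, for Actin). The size of the 0H count itself is open, because it changed with array weights and with the array left out. Leaving out replicates 1 and 2 of the 40 °C 0H group kept 1 array there. Fewer calls then follow from the lost replicates, so that setting cannot tell how large the ratio is. A different response to the storage temperature at 4H remains a candidate explanation, as a hypothesis found and tested on the same data, and the labels do not say whether the 4 groups were processed together.

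For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In probe sets the real split gave 3129 at 0H and 13068 at 4H with temperature, and 14457 at 25 °C and 15396 at 40 °C between 4H and 0H; in each of the 4 comparisons it was the 1 split of 10 with as many, and the highest other split gave 0 with limma. For called lists the real values and the highest other splits were 1 and 6 at 0H (9 of 10 splits gave as many), and 13 and 12 at 4H, 9 and 8 at 25 °C and 11 and 7 at 40 °C (1 of 10 in each).

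For the averaged effect and the interaction, 100 of 200 possible splits within the 0H and within the 4H arrays were drawn. Among the splits drawn the real one gave the most probe sets (1 of 100 in each). The averaged effect had 11731 against at most 10536 in another split, and the interaction 11469 against at most 10579. Splits that kept neither real grouping gave 0, so the high counts came from splits that kept the real grouping at 0H or at 4H. The splits thus test whether the arrays of the temperature groups differed at all. For that, chance can be excluded among the splits drawn only if the arrays are independent. The labels do not say whether the replicates came from independent seed lots. The splits cannot tell an effect of temperature from a difference in how the groups were processed. The splits also cannot test whether the temperature effects differ, so chance is not excluded for the interaction by them. The split that exchanges the temperatures in the 0H arrays alone was not drawn. By construction it turns the interaction into the averaged effect, with 11731, above the real 11469. Chance cannot be excluded for the number of called lists, as 12 of 100 splits gave at least the 11 of the averaged effect (highest other 14) and 11 of 100 the 11 of the interaction (highest other 15).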

How the results depend on the processing

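Median centring, setting values below log2 4 to 4 and leaving out arrays by their spike-ins were chosen after seeing the data. No named gene or gene list result reversed under any alternative. Of 299 named gene results 282 kept their call under all alternatives run. Most of the genes named at 0H did not. CML27, OsCDSP32, OsPht1;4, NAC067, OPR1, OPR5, ABCG39 and OPR10 lost it under at least 1 alternative with more than 1 array per group. RA14, PROLM25, cob, SSII-3, atpI and OsPP2C32 lost it only where 1 array was left at 40 °C. The other results that lost a call were OPR5 and MSRB3 in the interaction. Of 56 called lists 38 kept their call apart from the estimated correlation, with which camera called 0 lists in each of the 6 comparisons (1 and 1 at an unadjusted p under 0.05 for temperature at 0H and 4H, 4 and 4 for 4H with 0H at 25 °C and 40 °C, 2 for the average and 2 for the interaction). At 0H the count of 3129 probe sets became 5558 with array weights and 888 without the poly-A-high arrays, and ranged from 2079 to 3472 when 1 array was left out. The called lists at 0H (1) became 0 with values below log2 4 set to 4, 4 with no filter on low values and 3 without the spike-in-low arrays, and ranged from 1 to 3 with 1 array left out. Between 4H and 0H, the lists at 25 °C (9) became 15 with no filter, and those at 40 °C (11) became 7 with quantile normalization, 7 with median centring, 7 with values below log2 4 set to 4 and 6 to 11 with 1 array left out. The stricter filter at log2 6 gave 9525 probe sets at 25 °C and 10045 at 40 °C, with fewer tested. The correlation of the 4H effects (0.831) was 0.802 with no filter, 0.861 with the stricter filter, 0.812 with values below log2 4 set to 4 and 0.811 without the spike-in-low arrays. Apart from the filter at log2 6, the cause was not tested. On each array 25.5% to 27.7% of the probe sets lay above log2 4, and probe sets not above it in at least 3 arrays were not tested. Some tested ones lay below it in both groups compared (179, 473, 315 and 228 of the calls at 0H, at 4H, at 25 °C and at 40 °C), where a difference of signals gives no size.

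With the replicate block 2 lists were called at 0H in place of 1. All 56 called lists and 298 named gene results had the same call with the block as without it, and 1 named gene result gained a call. The correlations of same-numbered replicates behind the pairing check were 0.0310, 0.0961 and 0.139 for temperature at 0H, 0.0606, 0.163 and 0.213 at 4H, and −0.0517, 0.102 and 0.173 for 4H with 0H at 40 °C, so the numbers were not taken as pairs there. In none of the 4 comparisons did every array correlate best with its own number.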

Other observations

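Of the tests in this part, those of GBSS1, PROLM25 and RA14 and the settings with median centring and without the spike-in-low arrays were chosen after the result was seen. Between 4H and 0H at 25 °C, glycolysis and fermentation genes rose in 9 of 16 and fell in 6 (list adjusted p = 0.237): the aldolase FBA1 rose by 5.89 (SE 0.20) and the alcohol dehydrogenase Adh2 by 4.89 (SE 0.20). Of the sucrose synthases OsSUS4 changed by −2.30 (SE 0.08), while OsSUS3 rose by 4.90 (SE 0.12), OsSUS1 from 4.98 to 9.94 and OsSUS2 from 4.12 to 9.29. Their list had 10 of 15 genes higher and 4 lower (list adjusted p = 0.132). Tubulins and actins rose in 11 of 14 genes and fell in 3 (list adjusted p = 0.0637), and TUB4 rose by 2.32 (SE 0.09). Aquaporins, which carry water across membranes, fell in 8 of 10 genes and rose in 2 at each temperature (list adjusted p = 0.0767 at 25 °C and 0.0629 at 40 °C), with the seed-type TIP3-1 at −1.81 (SE 0.08) at 25 °C and −1.79 (SE 0.08) at 40 °C.

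In abscisic acid metabolism and signalling, 10 of 24 genes rose and 8 fell between 25 °C and 40 °C at 4H (9 fell adjusted over the list alone; list adjusted p = 0.207). The kinase gene OsSAPK5 rose by 2.52 (SE 0.14), the receptor gene OsPYL11 by 1.67 (SE 0.09), and OsPP2C51 was at −1.88 (SE 0.09). Auxin genes fell in 22 of 36 and rose in 7 (list adjusted p = 0.289). The 18S ribosomal RNA controls read 6.82 in replicate 3 of the 25 °C 4H group and 7.87 in replicate 3 of the 40 °C 0H group, and the hybridisation spike-ins read 8.63 and 7.72 in replicate 3 of the 25 °C groups at 0H and 4H, lowest within each group, and 8.35 to 8.65 in the 40 °C 0H arrays.

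The hypothesis that the axes kept at 40 °C changed in the same way between 0H and 4H but more slowly was tested on the 10492 probe sets called for both the averaged 4H effect and the interaction. It asked that over 80 percent have a difference opposed to the 4H effect, and 27.0% did (2830), 33.6% of those that rose at 4H and 20.5% of those that fell. The share was 28.2% with quantile normalization, 27.1% with median centring and 28.8% without the spike-in-low arrays, so a general slowing was not seen. The 4H effect was smaller at 40 °C in those 2830 probe sets and larger at 40 °C in the rest of the 10492. Over all probe sets the SD of the 4H changes was 1.54 at 25 °C and 1.86 at 40 °C, so there was no smaller change at 40 °C for the hypothesis to explain.

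GBSS1, PROLM25 and RA14, genes of the starchy endosperm, were higher at 40 °C at 0H. If starchy endosperm in the 40 °C samples were the cause, the 4 glutelins should rise by as much, but their median was 0.080 against 1.30 for PROLM25, and the highest, GLUD-1, was at 0.79. Storage transcripts read high in replicate 3 of the 25 °C 0H group, and without it these values were 0.44, 1.69 and 1.12. Taken per array, the median of the glutelins minus PROLM25 was lower at 40 °C by 1.24 (SE 0.19). Without that array it was lower by 1.28 (SE 0.27). RA14 and PROLM25 were chosen because they had the largest rises of the storage list, which by itself leaves smaller rises to its other members. The comparison therefore cannot decide whether starchy endosperm was the cause at 0H, in whole or in part. Storage transcripts also climbed together over replicates 1 to 3 of the 25 °C 4H group (RA14 9.13, 9.72 and 10.5, GLUB-5 7.07, 7.55 and 8.00). Between the temperatures at 4H, RA14 and PROLM25 differed by 0.22 each and GBSS1 by 0.76, and the glutelins by −0.35 (GLUD-1) to −1.25 (GLUA-1). An effect of the storage temperature on GBSS1, PROLM25 and RA14 stays open as an untested biological explanation, and so does a probe set match to related transcripts, since all 3 genes were read with _s_at or _x_at probe sets.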
